A study of Rattus norvegicus with 8 samples.

How the data were processed

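Cells from the urethra of female Sprague-Dawley rats were profiled with droplet-based single-cell RNA sequencing (10x Genomics 3′ chemistry on a NovaSeq instrument, per the labels' protocols). Tissue was digested with collagenases, a neutral protease and DNase, and dead cells were removed on magnetic columns before loading, per the labels' protocols. The labels name 8 samples, 1 per combination of treatment and age. The treatments were sham surgery, ovariectomy with balloon dilation (VBDO), VBDO with BAPN (β-aminopropionitrile, an inhibitor of lysyl oxidases), and VBDO with BAPN and MAP, an abbreviation the labels do not spell out. Each was sampled at 24 and 48 weeks of age. The design text plans 1 rat per group for sequencing, but its numbers of rats do not add up, so the number of rats behind a library is not taken as known.

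The authors deposited a single matrix of UMI counts (whole-number counts of unique molecular identifiers per gene and barcode, not normalized), with gene and barcode lists. The matrix holds 25557 genes, 173978 barcodes and 652943391 counts. The deposited count matrix was written by Cell Ranger 7.1.0 per the file headers, while Cell Ranger 3.1.0 and the genome build mRatBN7.2 are named per the submitters' processing notes. Whether reads from introns were counted is not given in the sources used here, and it affects the level of genes with long introns. No coordinates were used.

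Barcodes end in a number from 1 to 8, and each number was treated as a library. No source used here ties these numbers to the labelled samples, so the libraries carry no treatment or age, and the planned comparison of treatments within cell classes, with its 3 alternatives, was not made. Libraries are therefore described one by one, or by their lowest, median and highest value, with no test, p-value or mean ± SD of a group. A mean over libraries is used below only as the level of a class. At most 363 barcode sequences were shared by any pair of libraries. Taken as a share of the smaller library, the highest value was 1.10%, in another pair. Library totals ran from 41439693 UMIs in library 5 to 144169383 in library 4. Whether libraries were thinned to a common depth when they were joined is not given in the sources used here.

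Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial counts were kept (140599). Doublets were scored within each library against simulated doublets, and called above the minimum between the modes of the simulated scores, or as the top 8% where that called under 0.5%, which applied in libraries 1, 3, 6, 7 and 8. The 11672 called doublets (8.30%) were removed, leaving 128927 cells. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes and 30 principal components were taken, and cells were grouped by Leiden clustering at resolution 1.0 on 15 nearest neighbours. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9 and scikit-image 0.26.0 were used, and edgeR 4.0.16 in R 4.3.3 for TMM factors only.

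The 27 clusters were named by hand from fixed markers (189 of 203 in the table) and their leading genes, with the suffix "-like". A cluster stayed unnamed if the 10 genes with the highest fold over cells outside its class (5 CPM added to each side, and at least 20 counts) went against the name. Clusters 1, 4, 9, 24 and 26 stayed unnamed, the last because the fixed markers hold no set for the cell type that its leading genes point to. The immune cluster mixed several immune types and is called mixed immune.

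For gene levels, counts were summed per class and library, rows with the same symbol added together, and expressed as CPM, counts scaled to the same total in each sum. The level of a class is the mean over libraries with at least 50 of its cells. The 20 gene lists hold 316 genes, of which 306 were in the table. A list gene was counted as measured where its highest class reached 20 CPM. It was counted as separated where that class exceeded the second in every library holding both, with at least 3 such libraries, a criterion written after the counts were seen. To give the number that arises without class differences, class labels were shuffled within libraries 100 times. A gene was called defining if it was a fixed marker or among those 10 genes for a cluster of its leading class; a defining gene describes how the class was built and is no independent result.

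The named genes were, by a fixed rule, up to 4 per list with the largest ratio of the leading to the second class, up to 3 led by a class other than that of most of the list, and Lox, Esr1, Pgr and Eln in every case. Between libraries they were the 10 with the largest ratio of the highest to the lowest library in each of the 3 largest classes, at 50 counts and 50 CPM or more. The text gives a part of these, and some named genes are not reported here. Where the lowest library had under 3 counts, the ratio was taken against 3 counts in that library.

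Intervals are exact 95%: binomial for shares and Poisson for counts. A count of 0 is also given as the share that 3 counts would make. Both intervals cover counting error only, not the difference between animals. The epithelial marker load of a cell is the sum of the fixed urothelial and luminal markers per 10000 UMIs, called high in cells of other classes above 0.5 times the median of urothelial-like cells of the same library. Free RNA in the suspension also gives a low count of abundant genes in cells that do not make them.

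The counting of leading classes was tested on simulated data for 400 genes drawn with the real library sizes. The genes averaged at least 20 CPM over classes, and all classes without a lead had the same profile. Dispersion was fixed, with no library difference shared by classes, so the rates below hold for that setting only. The leading class was recovered for 89.6% of genes given a 1.5-fold lead, 100% at 2-fold and 100% at 4-fold. Of these genes, 14.9%, 43.3% and 72.7% met the separation criterion, against 0.5% of 200 genes with no lead. A further simulation drew identical library profiles with counting error only, without the dispersion above. In it 0 of 57 urothelial-like, 0 of 77 vascular endothelial-like and 1 of 49 luminal urothelial-like genes reached a 2-fold ratio between libraries. It therefore does not show how far libraries differ beyond the difference between animals.

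Alternatives fixed before the data were examined covered the cell filter, the mitochondrial limit, doublets, clustering resolution, components, centring on libraries, weighting of cells and libraries, TMM scaling, the CPM minimum, the cell minimum, background subtraction, thinning to 1000 UMIs per cell and leaving out each library. Alternatives added after seeing the data were a second random seed, counting clusters 1, 4 and 9 as urothelial-like, leaving out clusters 3, 11 and 14, leaving out cells with a high epithelial marker load, leaving out the adipocyte-like class, and classes from resolution 2.0.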

Results

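The series describes a single-cell atlas of the rat urethra after simulated birth injury. Its 8 samples, 1 per combination, cover 4 treatments at 2 ages. The counts come from 8 libraries told apart by barcode number, which could not be tied to those samples. What follows is an account of cell classes, of the genes that mark the processes the treatments address, and of how far the libraries differed. Cells analysed per library ranged from 8070 in library 5 to 27228 in library 4. The median depth per cell ranged from 2428 UMIs in library 3 to 4332.5 in library 5.

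The first question was which cell classes the tissue yielded. Epithelium dominated every library. Urothelial-like cells, which line the urinary tract, made up a median of 56.4% of cells (46.0% in library 1 to 67.9% in library 7). Luminal urothelial-like cells, the surface layer marked by Krt20, added a median of 3.87% (1.55% to 4.96%). Vascular endothelial-like cells were the largest class outside the epithelium, with a median of 8.53% (3.28% to 11.6%).

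Muscle and connective tissue were sparse and uneven. Fibroblast-like cells had a median of 1.70%, from 0.409% in library 5 (95% exact interval 0.282% to 0.574%) to 4.57% in library 6 (4.21% to 4.96%). Smooth muscle-like cells had a median of 0.812%, from 6 of 8070 cells in library 5 (0.0744%, 0.0273% to 0.162%) to 3.46% in library 6 (3.14% to 3.80%). Skeletal muscle-like cells ranged from 0.329% to 3.99%, and mixed immune-like cells from 0.809% to 3.38%. Neuroendocrine-like cells, an epithelial type that makes serotonin through Tph1, were found in all 8 libraries at 0.392% to 2.34%. Lymphatic endothelial-like cells had a median of 0.840% and adipocyte-like cells 0.164%.

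Glandular epithelial-like and keratinizing squamous-like cells had no cell in library 5. They were also rare elsewhere, with 1 glandular cell of 13735 in library 3 and 5 keratinizing squamous-like cells of 12076 in library 6. Glandular epithelial-like cells reached 2.50% in library 4 and 1.67% in library 8, but 0 of 8070 cells in library 5, which allows a share of up to 0.0372%, taken as 3 cells (exact 95% upper limit 0.0457%). Keratinizing squamous-like cells, of the kind that lines the vagina and outer urethra, reached 2.29% in library 7 and also 0 of 8070 cells in library 5. Unnamed clusters held 33.1%, 31.8%, 27.1%, 20.6%, 19.8%, 16.5%, 13.4% and 11.9% of cells in libraries 1 to 8, and mostly belonged to clusters 1, 4 and 9. Counting these 3 clusters as urothelial-like raised that class to a median of 78.2%, and admitting barcodes from 200 genes raised fibroblast-like cells to 5.97%. Dissociation, dead-cell removal and the filter set these shares, so they are shares of recovered cells, not of the tissue.

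**Figure D1:**
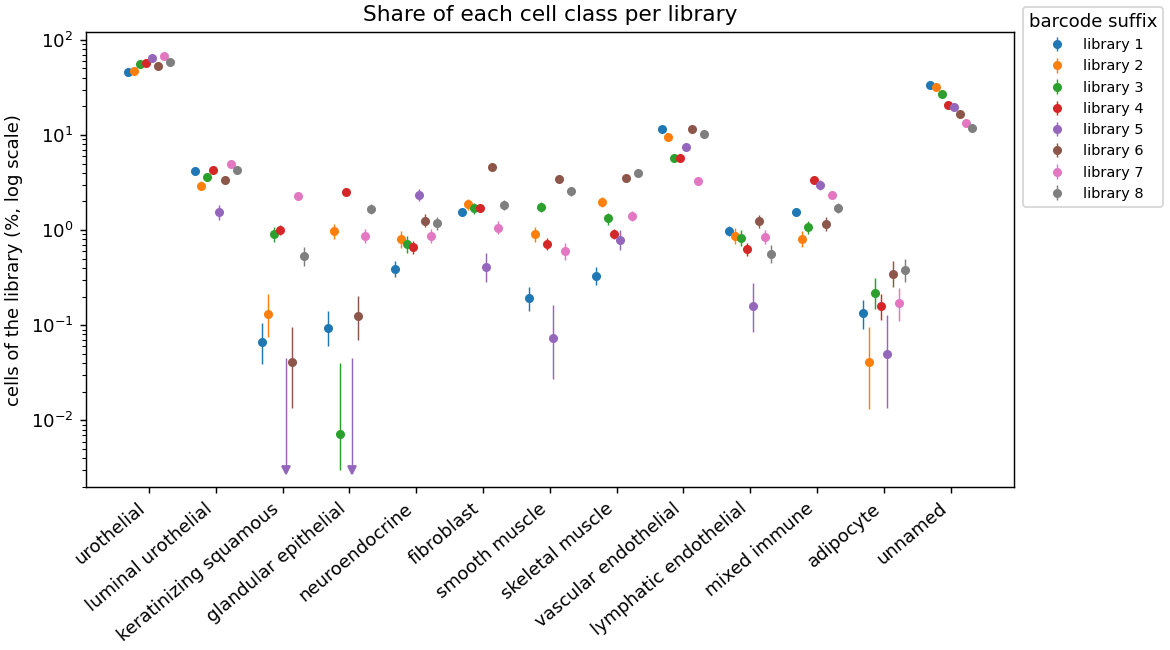
Share of each cell class in each of the 8 libraries, in percent on a log axis, with exact 95% binomial intervals; triangles mark a share of 0. Urothelial-like cells lie between 46.0% and 67.9% in all libraries, while glandular and keratinizing squamous-like cells are at 0 in library 5.

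The second question was which classes express the genes that ovariectomy, dilation and lysyl oxidase inhibition address. Of 235 list genes measured, 105 were separated, that is, higher in the leading class than in the second in every library with both. Adipocyte-like cells reached 50 cells in 1 library, fewer than the 3 needed. Genes with this class first or second, among them the 23 that it led, therefore could not be separated. Shuffled class labels gave a median of 2 and at most 21. The classes were clustered from these same counts, which the shuffling does not take into account. It therefore cannot show that a separated gene, defining or not, is independent of the clustering. With classes limited to libraries holding at least 200 of their cells, 69 were separated. Without cells of high epithelial marker load, 85 of the 105 were still separated with the same leading class. Of the 20 others, 2 changed their leading class and 11 kept it with a ratio to the second class within 1.5 times of the main one; beyond that bound the ratio was lower in 5 and higher in 2. In 9 of those that kept their leading class another class became second. Of the 105 genes, 36 were defining genes of their class and 69 were not. No replicate of a treatment exists, so only classes are compared. The counts of libraries compare classes within libraries. CPM values and log2 ratios compare means over each class's own libraries, and these can differ between the classes.

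Estrogen receptor transcripts were concentrated outside the urothelium. Esr1, the estrogen receptor alpha gene, averaged 2200 CPM in glandular epithelial-like cells (1636 to 2857, n = 4 libraries) and 1290 CPM in keratinizing squamous-like cells (944 to 2180, n = 4). The former was higher in 3 of 3 libraries holding both. Smooth muscle-like cells had 788 CPM (370 to 1237, n = 6) and fibroblast-like cells 235 CPM. Urothelial-like cells had 10.5 CPM (3.49 to 26.3, n = 8), below the 23.3 CPM of vascular endothelial-like cells. Esr1 is also among the 10 leading genes of the glandular cluster. Pgr, the progesterone receptor, had 150 CPM in glandular and 116 CPM in smooth muscle-like cells. The former was higher in only 3 of 4 libraries, so the order was not separated.

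Glandular epithelial-like cells led 3 of the 9 measured genes of the steroid receptor list. The third besides Esr1 and Pgr was Esr2, the estrogen receptor beta gene (30.2 CPM, 8.06 to 52.7, n = 4), named after its values were seen and not separated. Of the 9, 3 were separated. Besides Esr1 these were Pgrmc1, a membrane progesterone-binding protein, in luminal urothelial-like cells (183 against 77.4 CPM in urothelial-like cells, 8 of 8 libraries), and Fkbp5, a glucocorticoid-induced chaperone, in neuroendocrine-like cells (194 against 97.1 CPM, 8 of 8).

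**Figure D2:**
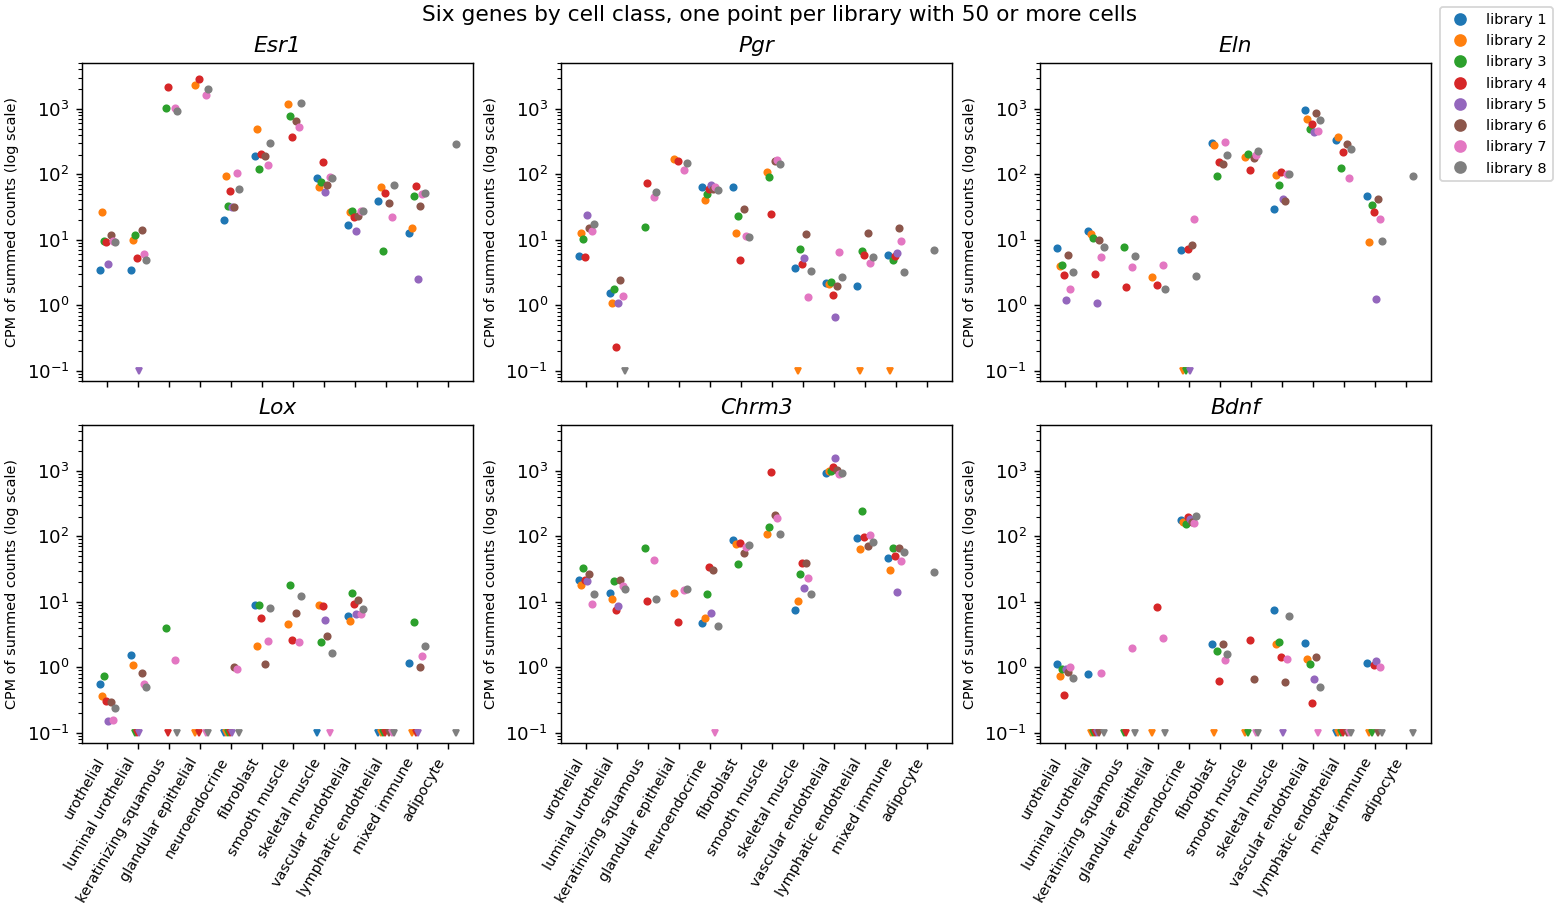
CPM of summed counts for Esr1, Pgr, Eln, Lox, Chrm3 and Bdnf by cell class, on a log axis, with 1 point per library holding at least 50 cells of the class; triangles mark a count of 0, drawn at the foot of the axis. Esr1 averages 2200 CPM in glandular epithelial-like and 10.5 CPM in urothelial-like cells.

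Lysyl oxidases crosslink collagen and elastin and are the targets of BAPN. Lox itself stayed under 20 CPM in every class, with 8.22 CPM in vascular endothelial-like cells (5.10 to 13.6, n = 8) and 7.79 CPM in smooth muscle-like cells (2.48 to 18.1, n = 6). Vascular cells were higher in 4 of 6 libraries, and the order of the means turned without library 4, 6 or 7 (log2 ratio 0.08, and -0.13, -0.03 and -0.06 without them). It also turned with pooled counts (-0.11) and with libraries of at least 200 cells (-0.58). Of the 5 members, 2 were measured and 0 were separated, though Loxl2, led by adipocyte-like cells, could not be. Loxl1 had 22.8 CPM in fibroblast-like and 14.9 CPM in smooth muscle-like cells, higher in the former in 4 of 6 libraries (log2 ratio 0.62, and 1.59 without cells of high epithelial load). Loxl2 had 77.2 CPM in smooth muscle-like cells, below 327 CPM in adipocyte-like cells, a class that reached 50 cells only in library 8 (log2 ratio 2.08, 1.14 with pooled counts and 0.81 with resolution 2.0 classes).

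Elastic fibre genes were divided among classes. Eln, the elastin gene, was highest in vascular endothelial-like cells (647 CPM, 448 to 968, n = 8), above lymphatic endothelial-like cells (240 CPM) in 7 of 7 libraries. In the lymphatic cluster 56.6% of cells carried a high epithelial marker load, and without such cells this log2 ratio fell from 1.43 to 0.27. The lymphatic level then rested on fewer libraries, and vascular endothelial-like cells were higher in 4 of 4. Fibroblast-like cells had 210 CPM and smooth muscle-like cells 184 CPM. Eln is a leading gene of cluster 18, 1 of the 2 vascular clusters. Of 13 measured members, 7 were separated, 5 of them not defining. Ltbp1, which anchors latent TGF-beta, led in neuroendocrine-like cells (916 against 469 CPM in smooth muscle-like cells, 6 of 6). Ltbp2 led in glandular cells (376 against 78.2 CPM, 3 of 3) and Efemp1, a fibulin, in vascular endothelial-like cells (758 against 385 CPM in fibroblast-like cells, 7 of 7). The log2 ratio of Efemp1 fell from 0.98 to 0.26 without cells of high epithelial load, and it was then not separated. Fbln1 led in fibroblast-like cells (171 against 13.8 CPM, 7 of 7; log2 ratio 3.63, and 4.52 without those cells) and is a marker of that class.

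In the list of fibrillar collagens and associated proteoglycans, fibroblast-like cells led 9 of 16 measured genes, with 8 of the 16 separated and 3 of these not defining. Of the 13 collagen genes among them, fibroblast-like cells led 7, and 5 were separated. All 5 separated genes led by fibroblast-like cells are defining. Of these Dcn, decorin, had 291 against 45.9 CPM in smooth muscle-like cells (6 of 6; log2 ratio 2.66, and 3.56 without cells of high epithelial load). The 3 that are not defining, Col6a1, Col6a2 and Bgn, were led by smooth muscle-like cells, and none of the 3 was separated without cells of high epithelial load. The log2 ratio to fibroblast-like cells then went from 0.70 to 0.18 for Col6a1 and from 0.56 to -0.15 for Col6a2. For Bgn it went from 1.525 to 0.826, and smooth muscle-like cells were still higher in 4 of 6 libraries. Col5a2 had 584 CPM in smooth muscle-like and 470 CPM in fibroblast-like cells and was not separated. Its order turned without cells of high epithelial load (log2 ratio 0.31 and -0.60). Of basement membrane genes, 5 of 18 measured were separated. Col4a6 had 1065 against 350 CPM and Col4a5 1104 against 427 CPM in smooth muscle and fibroblast-like cells, each in 6 of 6 libraries. Of the 18, 6 were led by smooth muscle-like and 6 by adipocyte-like cells. The latter 6 could not be separated, and their count fell to 0 without library 8. In fibroblast-like cells these levels were measured in a cluster of which 51.0% of cells carried a high epithelial marker load.

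Matrix-degrading enzymes were separated for 6 of 11 measured members. Mmp12, a macrophage elastase, had 38.4 CPM in mixed immune-like cells against 0.472 CPM in keratinizing squamous-like cells (4 of 4), a level that rests on library 4 alone. Mmp2, a gelatinase, had 46.9 CPM in fibroblast-like cells against 12.7 CPM in vascular endothelial-like cells (7 of 7; log2 ratio 1.89, and 2.67 without cells of high epithelial load). Adamts1 led in glandular cells (192 against 39.5 CPM, 4 of 4).

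Contractile genes followed their muscle class. All 15 smooth muscle genes were led by smooth muscle-like cells, 11 separated, and 14 of 15 skeletal genes by skeletal muscle-like cells. Of the skeletal list 12 were separated, and most of the separated genes in both lists are markers, with 2 and 3 separated genes respectively that are not defining. Tpm2, a tropomyosin of the skeletal list, led in smooth muscle-like cells (348 against 214 CPM, 6 of 6). Of 4 measured myogenic progenitor genes, Pax3 (370 against 9.29 CPM in fibroblast-like cells, 7 of 7; log2 ratio 5.32, and 4.31 without cells of high epithelial load) and Myf6 (39.7 against 0.413 CPM in smooth muscle-like cells, 6 of 6) led in skeletal muscle-like cells. The smooth muscle level of Myf6 rests on library 7 alone. Notch3 led in keratinizing squamous-like cells (230 against 123 CPM in glandular cells, 3 of 3) and counts as defining, since it is a fixed marker of pericytes. Pax7, the satellite cell regulator, had 29.3 CPM in the fibroblast-like cluster and 8.97 CPM in skeletal muscle-like cells, higher in the former in 6 of 7 libraries. Pax7 is a fixed satellite cell marker and was not separated. The other satellite cell markers of this list, named after their values were seen, stayed under 20 CPM. Chodl and Calcr were also highest in the fibroblast-like cluster, and Myf5, Myod1 and Cdh15 in skeletal muscle-like cells. Which cells of the fibroblast-like cluster hold the Pax7 counts was not tested. The log2 ratio of Pax7, 1.71, became 2.69 without cells of high epithelial load and 0.72 with libraries of at least 200 cells.

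Receptors that control urethral tone were not limited to smooth muscle. Chrm3, the muscarinic receptor M3, had 1065 CPM in vascular endothelial-like cells (909 to 1580, n = 8) against 285 CPM in smooth muscle-like cells (107 to 952, n = 6), higher in 6 of 6 libraries. Library 4 raised the smooth muscle level, and without it the log2 ratio went from 1.90 to 2.80. Gucy1a1, a subunit of the nitric oxide receptor, had 887 against 375 CPM in the same classes (6 of 6). Pde5a, which degrades cyclic GMP, led in smooth muscle-like cells (1214 against 124 CPM in neuroendocrine-like cells, 6 of 6). Of 17 members measured, 8 were separated and none of the 8 is defining.

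Signalling genes separated by class in part. In the growth factor list 8 of 16 measured genes were separated. Bdnf, a neurotrophin, had 177 CPM in neuroendocrine-like cells (156 to 205, n = 8), above 2.78 CPM in glandular cells in 4 of 4 libraries. Of the 38 counts in glandular cells 36 came from library 4, and without it the log2 ratio went from 5.99 to 7.53; with pooled counts it was 5.18. Vegfc, a lymphatic growth factor, had 317 CPM in vascular endothelial-like cells against 38.2 CPM in fibroblast-like cells (7 of 7), and is a defining gene of the vascular class. Its log2 ratio was 3.05, and 2.07 without cells of high epithelial load. In the TGF-beta list 8 of 15 were separated, 4 of them also without cells of high epithelial load. Tgfb1, Tgfbr3, Smad3 and Smad4, named after their values were seen, were the 4 lost, with log2 ratios that went from 0.79 to 0.56, 0.54 to 0.44, 0.64 to 0.64 and 0.39 to 0.39. For Smad4 lymphatic endothelial-like cells became second, and glandular cells were higher in 2 of 2 shared libraries, fewer than the 3 needed. Among those kept were Acvrl1 (183 against 45.0 CPM) and Eng (430 against 123 CPM) in vascular endothelial-like cells, each in 7 of 7. Without cells of high epithelial load the log2 ratios of Acvrl1 and Eng went from 2.03 to 1.30 and from 1.81 to 1.01. For Eng the second class, lymphatic endothelial-like cells, then rested on fewer libraries, and vascular endothelial-like cells were higher in 4 of 4. Tgfbr1 led in mixed immune-like cells (600 against 182 CPM, 6 of 6). In the Wnt and BMP list 5 of 16 were separated, and 2 of the 5, Bmp5 and Bmp2, without cells of high epithelial load. Besides Rspo3 the lost genes were Bmp4 (log2 ratio 0.82 and 0.03) and Wnt5a, whose ratio to fibroblast-like cells rose (0.20 and 0.46). For Wnt5a smooth muscle-like cells then became second, and luminal cells were higher in 4 of 6 libraries. Its leading class turned to urothelial-like without clusters 3, 11 and 14, and to adipocyte-like with resolution 2.0 classes. Bmp2, Bmp4 and Wnt5a were named after their values were seen. Bmp5 led in fibroblast-like cells (87.6 against 9.01 CPM, 6 of 6; log2 ratio 3.28, 4.10 without cells of high epithelial load and 2.40 with called doublets kept). Rspo3 led in smooth muscle-like cells (30.5 against 13.2 CPM in lymphatic cells, 6 of 6), an order that turned once cells with a high epithelial marker load were left out (log2 ratio 1.21 and -0.43) and that widened with called doublets kept (2.76). Without cells of high epithelial load the lymphatic level rested on fewer libraries, and lymphatic cells were higher in 2 of 3. With libraries of at least 200 cells the log2 ratio was 0.17. No library then held both classes, so this ratio does not compare them within a library. Of 14 mechanosensing genes 6 were separated. Piezo2, a mechanically gated channel, led in lymphatic endothelial-like cells (491 against 157 CPM in vascular ones, 7 of 7) and is a defining gene of that class. Its log2 ratio of 1.65 became 0.25 with called doublets kept and 3.15 without cells of high epithelial load. In the latter case the lymphatic level rested on fewer libraries. Fibroblast-like cells then became second, and lymphatic cells were higher than these in 4 of 4 libraries. Itgb1 led in smooth muscle-like cells (542 against 192 CPM, 6 of 6).

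In the antigen presentation list 7 of 8 measured genes were led by mixed immune-like cells and 6 were separated, as for Ciita, the class II regulator (249 against 10.0 CPM, 4 of 4; log2 ratio 4.64, 5.38 without cells of high epithelial load and 4.01 with pooled counts). Of 6 cytokine genes measured, 1 was separated, Il1b in mixed immune-like cells (20.8 against 1.46 CPM, 7 of 7). Its log2 ratio was 3.84, 2.86 with called doublets kept and 6.19 without cells of high epithelial load, where it was not separated. Of 15 urothelial barrier genes 9 were led by luminal cells and 4 were separated. Among the 4 were Grhl3, a barrier transcription factor (990 against 163 CPM in urothelial-like cells, 8 of 8), and the uroplakin Upk2 (198 against 27.4 CPM in mixed immune-like cells, 8 of 8), which is a marker. The log2 ratio of Upk2 was 2.85, and 3.57 without cells of high epithelial load, where lymphatic endothelial-like cells became second. In the stress list 2 of 11 were separated, Fosb in luminal cells (208 against 41.4 CPM, 7 of 7) and Jun in smooth muscle-like cells (64.0 CPM, above keratinizing squamous-like cells in 4 of 4). Neither was separated without cells of high epithelial load, and with each cell weighted alike Jun was led by keratinizing squamous-like cells. The log2 ratio of Jun stayed at 0.35 without cells of high epithelial load. The log2 ratio of Fosb to lymphatic cells was 2.33, 2.97 without library 8, 4.98 without cells of high epithelial load and 6.89 with libraries of at least 200 cells. The last 2 ratios rest on fewer lymphatic libraries. Lymphatic cells reach 200 only in library 1 (251 cells), where Fosb in luminal cells was lowest (21.1 CPM). The ratio of 6.89 sets that library against luminal cells of more libraries, so it mixes class and library. In the hypoxia list 1 of 8 was separated, the glucose transporter Slc2a1 in keratinizing squamous-like cells (127 against 29.5 CPM, 4 of 4). In the cell cycle list 1 of 6 was separated, Cdkn2a in glandular cells (20.9 against 6.84 CPM, 3 of 3; log2 ratio 1.61, 2.49 without library 8 and 2.85 with libraries of at least 200 cells).

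The third question was how far the same class differed between libraries. At least 2-fold differences between the highest and lowest library were found for 41 of 72 list genes in urothelial-like, 33 of 59 in luminal urothelial-like and 53 of 96 in vascular endothelial-like cells. Immediate early genes, which respond within minutes to stimuli including tissue dissociation, were among those with the largest ratios. Egr1 in urothelial-like cells ranged from 3.04 CPM in library 1 (2.58 to 3.56) to 141 CPM in library 2 (136 to 146); without library 1 the lowest value was 19.6 CPM. Fosb ranged from 3.52 CPM in library 5 to 119 CPM in library 8 (68.1 CPM without that library), and Atf3 from 19.0 CPM in library 7 to 252 CPM in library 3. In luminal cells Fosb ranged from 21.1 to 600 CPM and Egr1 from 5.52 to 234 CPM.

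A further group was highest in library 5. It comprised Cldn3 (2.24 to 104 CPM), a tight junction gene, Hspb1 (8.03 to 155 CPM), a small heat shock protein, B2m (49.8 to 527 CPM), Psca (62.1 to 556 CPM) and Cldn7 (10.6 to 91.3 CPM). Without library 5 the highest values were 53.4 CPM for Cldn3 and 79.6 CPM for Hspb1, and without library 3 the lowest value of B2m was 116 CPM and of Cldn3 3.61 CPM. In library 5, 62.6% of urothelial-like cells belonged to clusters 3, 11 and 14, which are rich in mitochondrial and ribosomal transcripts, against 6.68% in library 1. Without these clusters the ranges narrowed to 0.560 to 3.36 CPM for Cldn3, 7.54 to 24.8 CPM for Hspb1, 35.9 to 105 CPM for B2m and 33.7 to 115 CPM for Psca. The highest value of Egr1 was then 184 CPM, and the ranges of Fosb (4.33 to 208 CPM) and Atf3 (20.5 to 398 CPM) did not narrow.

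In vascular endothelial-like cells the largest ratios included Fosb (1.19 CPM in library 1, 53.4 CPM in library 7; lowest 7.24 CPM without library 1) and epithelial genes such as Upk2 (2.28 to 74.9 CPM, median 5.24) and Upk1a (46.1 to 352 CPM). The high end of Upk2 is library 4 alone, and without it the highest value was 16.3 CPM; without library 5 the lowest value of Upk1a was 78.6 CPM. In luminal cells the muscle gene Ttn ranged from 9.24 to 137 CPM (58.0 CPM at most without library 5). Uroplakins are genes of the urothelium, and the source of these counts in other classes was not tested. With a minimum of 20 counts and 20 CPM the numbers of genes at 2-fold were 65, 58 and 82 in urothelial, luminal and vascular endothelial-like cells.

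**Figure D3:**
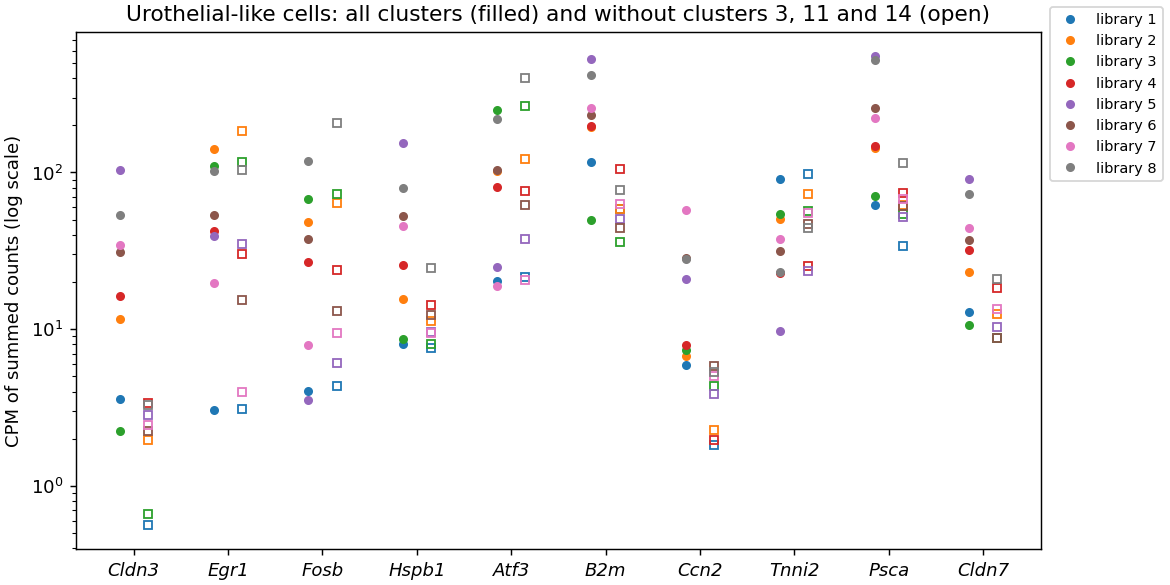
CPM of the 10 list genes with the largest ratio between libraries in urothelial-like cells, on a log axis, 1 point per library; filled circles are all clusters and open squares leave out clusters 3, 11 and 14. B2m runs from 49.8 to 527 CPM with all clusters and from 35.9 to 105 CPM without the 3 clusters.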

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

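Of the tests in this part, those of long genes and of other milk genes were stated before their values were seen, and the tests of depth, free RNA and doublets after the result they address. The libraries carry no treatment or age, so no biological explanation from the design was tested.

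Casein genes gave a signal in data that no comparison used. Unnamed cluster 24 held 947 counts of Csn2 and 509 of Csn1s1, in library 1 alone. Library 1 had 88 cells with at least 10 UMIs of Csn2, Csn1s1 and Csn3 (54 of them in cluster 24); a background even over UMIs gives 0.000623 such cells in that library, which argues against free RNA as the source of these cells. An earlier ratio test was dropped because the cells had been chosen by casein count, and 2410 cells of library 1 had at least 1 casein UMI; the 88 cells held 36.0% of its casein UMIs, and free RNA stays open for the rest. Of 6 other milk genes, 5 had at least 3 counts and were at least 10-fold above the other cells of library 1 (Wap had 2 counts, 8.94 against 0.109 CPM), including Csn1s2a (375 against 0.907 CPM), Xdh just so (304 against 30.2 CPM) and Lalba on 4 counts, so milk-producing epithelium in the tissue piece is a candidate source.

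Unnamed cluster 26 (133 cells) gave a further signal outside the comparisons. It held 987 counts of Pou2f3, 719 of Gnat3, 374 of Trpm5 and 6527 of Dclk1. All other clusters together held 1171, 89, 89 and 6972 counts of these genes.

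Urothelial-like cells fell into clusters rich (3, 11 and 14) and poor in ribosomal and mitochondrial transcripts. Among cells of 2000 to 4000 UMIs the mitochondrial share was at least 4.48 times higher in the rich clusters in each of the 8 libraries, which argues against depth as its cause. For ribosomal protein genes that ratio ran from 1.24 in library 2 to 13.5 in library 5, which leaves depth open for library 2. Library 3, at 1.60, also fell short of the 2-fold bound set against depth. Nuclei or cytoplasm-poor profiles in the poor clusters would raise 9 very long genes there over 1.5 times in every library, and their ratio ran from 0.929 in library 2 to 1.66 in library 5, the only 1 of the 8 past that bound. Outside library 2 the long genes were higher in the poor clusters, from 1.15 in library 1 upward. Abundant cytosolic mRNAs were lower there in all 8 libraries (ratio 0.0779 to 0.820), though library 2, at 0.820, missed the bound set for them. The explanation stays open, and not for library 5 alone. The other named classes had ribosomal shares of 0.316% (smooth muscle-like cluster 19) to 1.00% (keratinizing squamous-like cluster 23), against 2.04% in cluster 3. It was not tested for those classes.

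Fibroblast, mixed immune and lymphatic clusters carried epithelial transcripts, with a high marker load in 51.0%, 45.2% and 56.6% of cells, against 6.16% of vascular endothelial, 9.36% of smooth muscle and 17.1% of skeletal muscle-like cells; of 239 adipocyte-like cells it was 60.3%, with a lower doublet score in cells of high load (0.0557 against 0.118). Free RNA alone should reach all these classes alike. Their median load was 1.98 to 5.76 times that of muscle and vascular clusters in 7 libraries, just under the 2-fold bound set for library 4, and library 5 gave no ratio because its reference median was 0. Cells of high load had both more UMIs and a higher doublet score in 63.6% of 22 pairs of cluster and library, short of the 80% set for doublets, while UMIs alone were higher in 21 of the 22. Both explanations stay open.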

How the results depend on the processing

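Chosen after seeing the data were the second seed, clusters 1, 4 and 9, high epithelial load, clusters 3, 11 and 14, the adipocyte-like class and resolution 2.0 for lists; the other alternatives were fixed before the data were examined. The 3 planned for treatments were not run. Of the 105 separated genes, 102 to 105 kept their leading class in the 21 alternatives that recomputed class levels. The alternatives of the CPM minimum and of the adipocyte-like class could not change it, by construction. Keeping the leading class is also less than staying separated. For the other clustering, filter, seed and thinning alternatives this count was not made. The 3 lost at 200 cells were led by neuroendocrine-like cells, which reach 200 in no library. TMM factors shifted classes by -0.23 to 0.25 (log2). Depth limits the small classes, and the adipocyte-like class rests on library 8. Unless said otherwise, the cause was not tested. No paired analysis of treatments and ages was possible because no library is tied to a sample. Classes were compared within libraries in the counts of libraries only. The log2 ratios compare means over each class's own libraries.

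The median urothelial-like share (56.4%) became 53.5% at resolution 0.5, 60.4% with seed 2, 62.4% with 15 components, 61.5% with centring, 59.2% at a 10% mitochondrial limit, 52.4% with doublets kept, 47.4% with the loose filter and 78.2% with clusters 1, 4 and 9. With doublets kept, smooth muscle was 1.24%, skeletal muscle 1.66% and vascular endothelial 9.20%. With the loose filter, luminal was 3.25%, fibroblast 5.97%, smooth muscle 0.972% and vascular endothelial 9.77%. Leaving out each library gave 55.2% to 57.7% for urothelial and 7.50% to 9.57% for vascular endothelial-like cells.

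With at least 200 cells per library, where fewer libraries qualify, 69 genes were separated. List genes led by the list's usual class changed as follows, main count first. With each cell weighted alike, mechanosensing (3) was 1, Wnt and BMP (5) 8 and cell cycle (2) 1. With pooled counts, elastic fibre (4) was 2, basement membrane (6) 3, cytokines (2) 0 and hypoxia (4) 2. With doublets kept, elastic fibre was 2, mechanosensing 1 and cytokines 1. With TMM, elastic fibre was 2, mechanosensing 1, cytokines 1, hypoxia 2 and cell cycle 0. At 50 CPM, elastic fibre was 2, myogenic (2) 1, cytokines 1, Wnt and BMP 3 and cell cycle 0. With no minimum, myogenic was 7, cytokines 9 and Wnt and BMP 9. With 200 cells, lysyl oxidase (1) was 0, basement membrane 0, cytokines 1, hypoxia 2 and cell cycle 1. Without high epithelial load, lysyl oxidase was 0, basement membrane 0, TGF-beta (5) 3 and Wnt and BMP 9, and the log2 ratio of Rspo3 turned to -0.43. Without clusters 3, 11 and 14, mechanosensing was 1. Without the adipocyte-like class, lysyl oxidase and basement membrane were 0 by construction. At resolution 2.0, basement membrane was 2 and hypoxia 2. Leaving out each library gave 0 to 6 for basement membrane and 0 to 1 for lysyl oxidase (0 without library 8), 1 to 2 for cytokines, 2 to 5 for stress genes (4), 1 to 3 for mechanosensing and 1 to 3 for cell cycle.

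At 20 counts and 20 CPM, where more low genes enter, genes differing at least 2-fold between libraries rose from 41 to 65 (urothelial), 53 to 82 (vascular endothelial) and 33 to 58 (luminal).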

Other observations

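All genes in this part were chosen after their values were seen. Cluster 26 was found in all 8 libraries, at 0.00392% to 0.257% of cells, but with only 1 cell in library 1 and 2 in library 3. Its mean doublet score, 0.124, was the highest of the 27 clusters, and whether it holds doublets was not tested. Its leading genes are those of chemosensory tuft cells. Pou2f3, a transcription factor of these cells, had 1381 CPM there against 2.21 CPM in all other cells. Gnat3, a taste G protein subunit, had 1006 CPM, and the cluster held 89.0% of its counts. Trpm5, a channel of taste signalling, had 523 CPM, and Alox5, which starts leukotriene synthesis, 539 CPM against 1.22 CPM. Il25, a tuft cell cytokine of other epithelia, had 0 counts in the cluster and only 12 in all other clusters.

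Cluster 24 held further genes besides the caseins. Ascl3, an ionocyte transcription factor, had 42.1 CPM in the cluster against 0.142 CPM elsewhere, with counts in 5 libraries. Hepacam2 had 380 CPM against 6.52 CPM, with counts in 8 libraries.

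Cluster 11, with 8.44% of counts from ribosomal protein genes, held 1626 cells of library 5 and 1243 of library 8, but 1, 2 and 0 cells of libraries 1, 2 and 3. The share of cells over 3% mitochondrial counts was 33.3% in library 5 and 6.81% in library 2. Unnamed cluster 1, led by the haemoglobin genes Hba-a2 and Hbb-b1 at a median depth of 1515 UMIs, made up 18.7% of library 1 and 1.07% of library 5.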
